A study of Mus musculus and Homo sapiens and Drosophila melanogaster with 76 samples.

How the data were processed

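Chromatin immunoprecipitation and sequencing (ChIP-seq) peak lists were analysed from mouse embryonic stem cells and from the human colon cancer cell line HCT116. The mouse cells were the F123 line carrying CTCF fused to an auxin-inducible degron (CTCF-AID), a tag through which auxin directs a protein to the proteasome. They were left untreated, treated with 500 µM auxin for 48 h, treated with 1 µM flavopiridol, an inhibitor of the kinase that releases paused RNA polymerase II, for 6 to 8 h, or treated with both. In each of these 4 conditions the antibodies were against CTCF, the cohesin subunit RAD21, and RNA polymerase II phosphorylated at serine 5 (S5P) or serine 2 (S2P) of its C-terminal domain. A list for topoisomerase TOP2B came from F123 cells. HCT116 cells were untreated or treated with 500 nM decitabine (DAC), a DNA methyltransferase inhibitor, for 72 h, with antibodies against CTCF, the cohesin subunit SMC3, trimethylated histone H3 lysine 4 (H3K4me3) and S5P. Groups were taken from the sample titles and protocols. The other 51 of the 76 samples of the series, among them the CAP-C libraries, were not analysed here.

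The tools named per the submitters' processing notes are BWA 0.7.12, Picard 2.2.2, Juicer 0.7.0, MACS2, bedtools 2.27 and, except for TOP2B, cutadapt; which step each served is not given in the sources used here. The notes list mm10, hg19 and dm3 together for most libraries, and mouse lists were read as mm10 and human lists as hg19. Whether an input library was used, whether duplicates were removed from these libraries and how their peak threshold was set are not given in the sources used here. Each deposited list holds 1 line per peak, with a fold enrichment over background (a ratio), a −log10 p-value and a −log10 q-value, the offset of the summit, and an integer score that equals 10 times the −log10 q, rounded down, in all but 12 of the 588295 deposited peaks. The weakest peak of every deposited list had a −log10 q of 1.30 or more. Each list belongs to 1 sample in the labels, so peaks are taken as called per sample. Fold and score are the authors' values of a peak and were used to describe, rank or filter peaks within its list. Fold also entered the estimate of pileup and background described below.

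Peaks on assembled chromosomes were kept, which left out between 0 and 999 peaks per list, and overlapping peaks of a list were merged. A peak counted as kept, or as lying at a peak of another list, when the intervals shared at least 1 bp. Shares are given with exact (Clopper-Pearson) binomial 95% intervals, and differences of shares with Newcombe intervals. These intervals cover counting error over peaks only. Every group and antibody held 1 library, so no difference between conditions has a replicate check and no p-value is given. Shares expected by position were taken from 100 circular shifts of a list along each chromosome, with the chromosome length set to the last peak end of any list. Lists were also divided into 10 equal parts by fold. Regions holding a peak in all 16 mouse lists of the 4 conditions, or in all 8 human lists, were identified and the shares were recomputed without them.

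The depth of a library is not stated in the lists. The deposited fold and −log10 p values of the 24 lists other than TOP2B could be written, to within 0.002 in −log10 p at 99.9967% or more of the peaks, as (k + 1) / (b + 1) and the Poisson tail of a whole pileup k over a background b, which returned k and b for each peak. The commonest b of a list was taken as its background pileup and the width of its smallest peak as the fragment length. Their ratio gave the depth relative to the control library of the same antibody. This estimate assumes that background reads are alike in both libraries. It ranged from 0.506 for S5P in DAC to 1.67 for RAD21 in auxin plus flavopiridol. For auxin CTCF it was 0.602, with a smallest peak of 48 bp against 154 bp in the control, which together lowered the background pileup to 0.188 of the control's. A caller working at such a level misses weak sites, so fewer peaks do not by themselves show less binding. For this reason the share of control peaks that would pass the weakest p-value of the treated list, if only the background level differed, was computed by scaling each control pileup and summing Poisson probabilities. The procedures were tested on simulated data. On lists with the levels of control and auxin CTCF and no site lost, 42.1% of 69307 sites were kept against 42.3% expected. With 30% of sites removed, 31.0% of those with an expected probability over 99% were absent. For the RAD21 levels without loss, 96.8% of 25800 sites were kept against 94.5% expected. The simulated counts came from the same Poisson model as the expected shares, so they test the computation and not real libraries. For HCT116 CTCF in DAC, at 1.06 times the control depth, the weakest of the 10 parts by fold was kept at 56.7% against 87.4% expected. A share below the expected one may therefore hold variation between libraries as well as loss of sites. Overlaps of simulated lists were returned with 0 errors in 1480 comparisons, and 4 of 2982 simulated pileups were returned wrongly.

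Mouse genes came from the RefSeq table of GRCm38.p6, the assembly called mm10, with 21883 protein-coding genes on assembled chromosomes. The table used gives no strand. The planned window of 1000 bp around transcription starts was therefore replaced by 1000 bp on each side of either gene end, so that a gene with a peak at an end may hold it at its start or its finish. Genes named in the text were fixed by rule before the data were examined, as were the comparisons, the overlap and its alternatives. They are the 10 genes with the strongest control peak and none after treatment, the 10 strongest with a peak only after treatment, and the 10 strongest kept, leaving out clone names. In the smaller comparisons only the first of each 10 are printed, a choice made after the values were seen. Counts are given for 7 gene lists: pluripotency, housekeeping, immediate early and short-lived, fibroblast (the feeder cell type), lineage, imprinted, and CTCF with cohesin and topoisomerase. All 108 genes of these lists were found in the table. A gene counted as kept when both lists had a peak at it, whether or not the peaks overlapped. Single members named in the text were chosen after their values were seen. For CTCF, RAD21 and TOP2B a peak in the gene body also counted. A list was described by the percentile of its count among 10000 random lists of its size. These were drawn from genes of the same control state, except for TOP2B, where they were drawn from all genes used. The draws were not matched for peak strength, gene length or gene activity, so a high or low percentile may reflect these. The percentiles were not corrected for the number of lists and comparisons. No human annotation was used here, so HCT116 sites are named by hg19 coordinates, 5 per kind, leaving out chromosome Y, and the human gene lists were not used. The alternatives fixed beforehand were a −log10 q of at least 5, an overlap of at least 50% of both peaks, lists shortened to equal length by p-value, and gene windows of 500 and 2000 bp. The removal of regions found in all lists, the expected shares and the use of TOP2B to mark a gene end were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.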

Results

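The data comprised 25 peak lists from as many ChIP-seq libraries, 16 from CTCF-AID mouse embryonic stem cells, 1 for TOP2B in F123 cells and 8 from HCT116 cells. Each condition was represented by 1 library per antibody, so every difference below compares single libraries and carries no replicate error. On assembled chromosomes the control mouse lists held 71572 peaks for CTCF, 26704 for RAD21, 5449 for S5P and 15270 for S2P, covering 20.1, 6.73, 2.05 and 8.71 Mb. The median peak summit of these lists rested on 18, 16, 23 and 43 overlapping fragments. CTCF and RAD21 peaks lay mostly away from gene ends (12.9% and 8.82% at an end), whereas 60.9% of S5P and 39.3% of S2P peaks were at the end of a protein-coding gene.

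**Figure D1:**
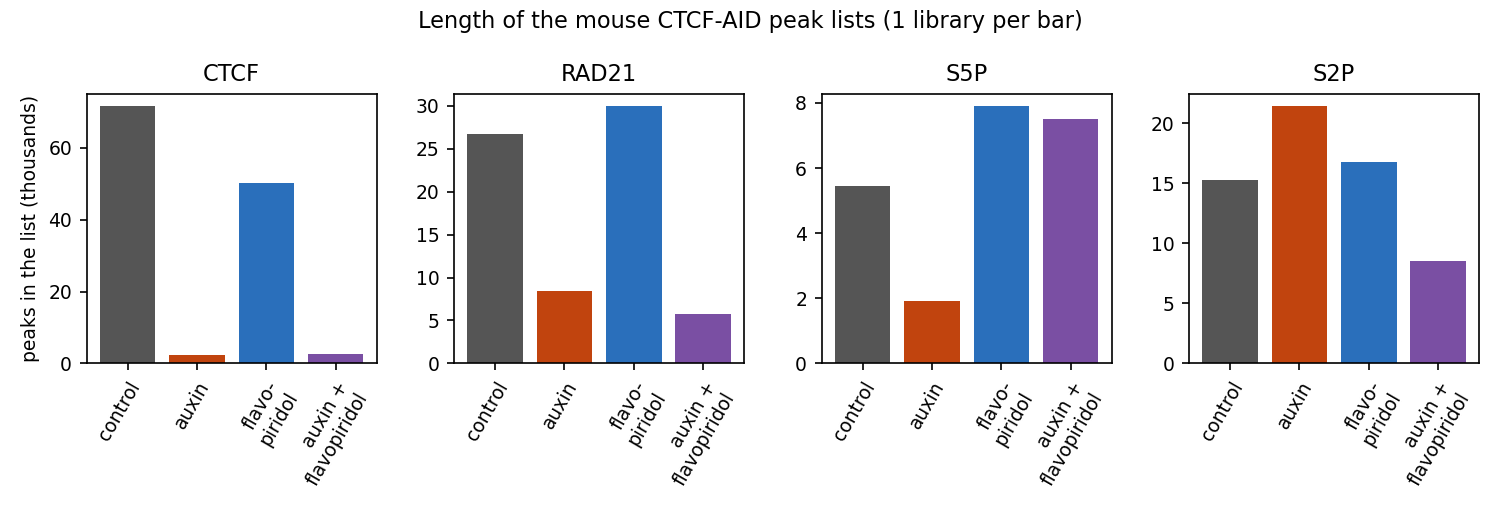
Number of peaks (axis scaled by 1000) in the mouse CTCF-AID lists for 4 antibodies (panels, each with its own vertical axis) and 4 conditions (bars, 1 library each). The CTCF bars fall from 71572 peaks in the control to 2216 in auxin, and the RAD21 bars from 26704 to 8421.

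The first comparison asked what auxin, which targets CTCF for degradation, did to CTCF occupancy. Almost all CTCF peaks were absent after auxin: 944 of 71572 control peaks were kept, 1.32% (95% interval 1.24 to 1.41). The auxin list held 2216 peaks covering 0.161 Mb, and 53.7% of them did not overlap a control peak. Loss reached the strongest sites, with 3.65% of the top decile of control peaks kept, where the background level alone would have left 96.3%. Among the 3503 control peaks with an expected probability over 99%, 94.5% were absent. The share kept by chance position was 0.0265%. With lists of equal length 7.40% of control peaks were kept, and with an overlap of 50% of both peaks 0.106%. The latter value reflects peak width: the median auxin peak was 53 bp wide and the smallest control peak 154 bp. A peak of that median width cannot cover 50% of any control peak.

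Genes with a CTCF peak at an end fell from 8364 to 101. The strongest peaks lost were at Map3k15, Lsm11, Thg1l, Rbm17, Rapgef1, Rab2b, Tox4, Erc2, Prss48 and Mterf1a, with control folds from 37.0 down to 32.1. The peak at Map3k15, on the X chromosome at 159987868 to 159988277 (mm10), spanned the left end of the annotated gene. At 77 genes both lists had a peak, and at 57 of them the strongest peaks of both lists overlapped. The strongest in the control were Ddx47, Med4, Wls, Sh3glb1, Crybg1, Wrap53, Trp53, Mrps33, Nipsnap2 and Tram1. Med4 encodes a Mediator subunit, and the Wls peak lies in a region present in all 16 mouse lists. Peaks seen only in auxin had folds in their own list from 9.81 at Ccdc184 and Spn to 6.54 at Mmp25. The others were at Plekhg4, Bnip2, Gtf2a2, Gcgr, Slc39a4, Nfatc3 and Olfr389. Of the fixed lists, CTCF peaks in or at a gene were lost from all 17 pluripotency genes that had a peak, such as Pou5f1, Sox2, Nanog and Esrrb, and from all 13 imprinted, 12 lineage, 11 immediate early, 9 fibroblast and 13 CTCF and cohesin genes. Housekeeping genes went from 12 to 1, the elongation factor gene Eef2. Random lists kept CTCF at a median of 0 or 1 genes, so a count of 0 could not set a list apart from them.

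CTCF peaks at polymerase were kept in auxin more often than others. Of control CTCF peaks at a control S5P peak, 22.1% (20.2 to 24.0) of 1858 were kept, against 0.766% of 69714 others, but 289 of the 410 kept lay in regions found in all lists, which are kept and at S5P by definition. Without those regions the share was 7.71% (6.44 to 9.14) of 1569, and the mean difference within deciles of equal CTCF fold was 7.36 percentage points instead of 18.8. CTCF peaks at RAD21 peaks were kept in 2.79% of cases, or 1.56% without the regions, against 0.620% of others, and those at TOP2B peaks in 1.55% against 1.31%, or 0.891% against 0.920%.

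The question for RAD21 was whether cohesin sites follow CTCF. After auxin the RAD21 list held 8421 peaks, 28.4% (27.9 to 28.9) of control RAD21 peaks were kept, and 90.3% of what remained lay at control sites. By the estimate from the background, the auxin RAD21 library was not shallower than its control. It had 1.13 times the control's estimated depth and 1.00 times its background pileup, and 96.1% of peaks would have been kept on that ground. With lists of equal length, the share kept was 60.9%. Retention followed strength, from 8.12% in the lowest decile by fold through 17.5% in the fifth to 80% in the top decile. In the control, 86.7% of RAD21 peaks were at a CTCF peak, and 86.3% of the RAD21 peaks left in auxin were at these control CTCF sites, although only 8.62% were at a peak of the auxin CTCF list. RAD21 sites with control CTCF were kept in 29.8% of 23141 cases and sites without it in 19.2% of 3563, a difference of 10.6 percentage points (9.17 to 12.01). Within deciles of equal RAD21 fold the mean difference was 4.15 points, positive in 8 deciles. Of the 3563 sites without control CTCF, 79.5% (78.1 to 80.8) were at a CTCF peak of the flavopiridol list.

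RAD21 peaks at a gene end went from 2461 to 783 genes. Among the strongest lost were those at Plcd3 and Acbd4, which share a peak, Adprhl1, Gprc5b, Spi1, Gucy2g, Irak2, Xkrx and Tmem230, with control folds of 16.7 to 15.1. Spi1 encodes the blood transcription factor PU.1. Those kept were led by Wls, Oasl1, Arhgap22, Abca14, Ccdc110, Ebf1, Dhx8, Cers5, Slc4a3 and Apob, of which Wls, Oasl1 and Cers5 lie in regions found in all lists. RAD21 peaks seen only in auxin were at Tmed4, Plekhg1, Cep120, Vmn2r4, M1ap, Etv3l, Abca2, Bicd1, Avpr1b and Obi1. Among the fixed lists, imprinted genes kept RAD21 at 5 of 8 genes, Snrpn, Grb10, Peg10, Meg3 and Inpp5f, at the 93.9th percentile of random lists. Pluripotency genes kept 1 of 5 (Esrrb), lineage genes 1 of 5 (Neurog2), fibroblast genes 2 of 6, the CTCF and cohesin list 1 of 6 (Top2b itself), immediate early genes 1 of 3 and housekeeping genes 1 of 1, with percentiles from 20.6 to 82.8.

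RAD21 peaks at S5P peaks were fewer after auxin, 641 against 751 in the control, but made up a larger share of the shorter RAD21 list, 7.61% against 2.81%, a difference of 4.80 points (4.22 to 5.42). Set against the control S5P list the auxin share was 7.99%, so the difference did not hinge on the shorter auxin S5P list. Without the regions found in all lists it was 2.59 points, and with lists of equal length 10.8.

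**Figure D2:**
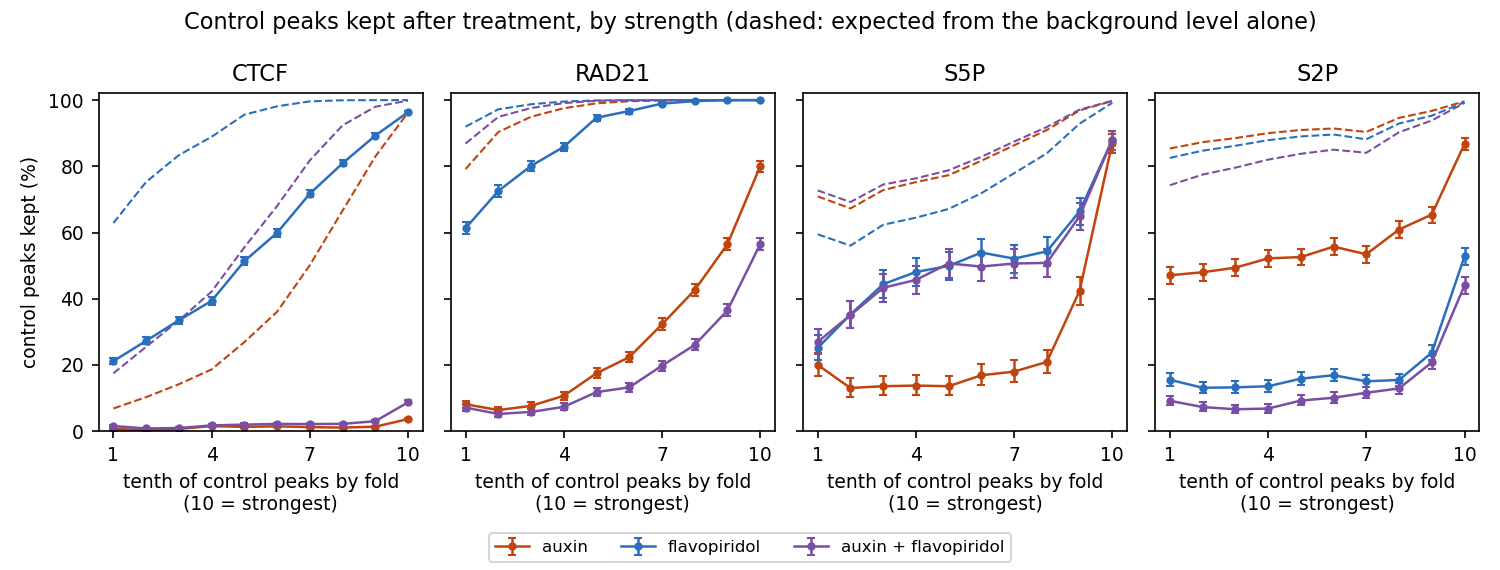
Percent of control peaks kept after each treatment (vertical axis) by decile of the control list ranked by fold (horizontal axis, 10 being the strongest), for 4 antibodies in mouse CTCF-AID cells, 1 library per condition. Points carry exact binomial 95% intervals and dashed lines give the share expected if only the background level differed; the top decile of RAD21 peaks was kept at 80% in auxin and 100% in flavopiridol, and that of CTCF at 3.65% and 96.4%.

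The comparison of flavopiridol alone with the control asked how CTCF and cohesin sites fared under this inhibitor. Whether polymerase was held from elongating was not measured here. RAD21 was largely retained: 89.0% (88.6 to 89.4) of control peaks were kept, including every peak of the top decile, and the list grew to 29942 peaks with 20.8% outside control sites. The flavopiridol RAD21 library had 1.32 times the control depth. Of its 15110 peaks with an expected probability over 99% in the control, 323 (2.14%) were absent there, so the new peaks were mostly weak sites. CTCF was retained less, at 57.1% (56.7 to 57.4) of control peaks, with 50243 peaks in the list. Its library had 0.753 of the control depth, at which 90.4% would have been kept. The share kept differed between CTCF sites with and without cohesin. CTCF peaks at RAD21 peaks were kept in 95.8% of 23030 cases and the remainder in 38.7% of 48542. Within deciles of equal CTCF fold the mean difference was 47.2 points, positive in all 10 deciles. A split in the same direction was present in HCT116 cells. There, 73.5% of control CTCF peaks kept in DAC were at a control SMC3 peak, against 17.0% of those not kept. The split is therefore not particular to flavopiridol. CTCF peaks at TOP2B peaks were kept less often than others, 43.9% against 57.7%, with a mean difference within deciles of −14.4 points, whereas with both drugs they were kept more often, 6.61% against 2.33%, with a mean difference of 3.29 points. CTCF peaks at S5P peaks were kept in 54.8% of cases in flavopiridol, or 46.5% without the regions found in all lists, against 57.1% of others. RAD21 sites with CTCF were kept in 90.6% and those without in 78.6%, a difference of 11.97 points (10.6 to 13.4), or 6.28 at a −log10 q of at least 5. The share of RAD21 peaks at S5P peaks was 2.67%, a difference from the control of −0.140 points (−0.411 to 0.129), which was −0.0352 at a −log10 q of at least 5, −0.00584 with an overlap of 50% of both peaks, −0.716 with lists of equal length and 0.0156 without the regions found in all lists.

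At gene ends, CTCF was found in both lists at 4696 of 8364 genes and RAD21 at 2111 of 2461, with overlapping strongest peaks at 4252 and 2041 of them. The strongest CTCF peaks lost were at Tpbgl, Klf1, Mboat4, Ndufa11, S100a14, Rnf112, Topaz1, Septin7, Cav1 and Stkld1, with folds from 22.4 to 18.2, and the strongest seen only in flavopiridol at Pik3r2, Camk2a, Ipcef1, Ube2s, Jchain, Tmem87b, Tes, Gprc5b, Olfr1441 and Add3. Klf1 encodes an erythroid transcription factor and Camk2a a neuronal kinase. The strongest kept were Map3k15, Lsm11, Thg1l and Ddx47, whose folds in flavopiridol were 29.5, 29.3, 29.3 and 29.99. RAD21 was lost at Xkrx and Tmem230 among others and appeared at Skap2, Fgf1 and Lif, the cytokine that keeps mouse stem cells undifferentiated. CTCF was kept in 13 of 17 pluripotency genes, 10 of 12 lineage genes, 9 of 13 imprinted genes, 8 of 12 housekeeping genes, 7 of 11 immediate early genes, 8 of 9 fibroblast genes and 11 of 13 CTCF and cohesin genes, with percentiles from 10.5 to 72.4. RAD21 was gained in 4 of 12 immediate early genes, Jun, Egr1, Atf3 and Dusp1, at the 99.1th percentile of random lists, where the median was 1. It was gained in 2 of 15 pluripotency, 2 of 14 housekeeping, 2 of 10 lineage, 1 of 7 imprinted, 1 of 7 CTCF and cohesin and 0 of 9 fibroblast genes. These gains were seen in a library of 1.32 times the control depth.

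For polymerase, flavopiridol changed where S2P was found more than how many peaks it had. The S2P list held 16773 peaks against 15270, yet 19.5% (18.9 to 20.2) of control S2P peaks were kept and 82.8% of flavopiridol peaks were at new positions. With an overlap of 50% of both peaks, 8.61% were kept. The S5P list lengthened to 7896 peaks, 51.8% (50.4 to 53.1) of control S5P peaks were kept and 63.8% of the list was new. Of S2P peaks, 14.4% were at an S5P peak in the control and 38.1% (37.4 to 38.8) in flavopiridol, where the highest value in shifted lists was 0.405%. Set against the control S5P list the flavopiridol share was 21.03% (20.4 to 21.7). Control S2P peaks were at the flavopiridol S5P list in 8.74%, so the rise cannot be assigned to a change of either list alone. In auxin without flavopiridol the shares of S2P peaks were 6.72% at auxin and 18.3% at control S5P peaks. Of control S5P peaks, 43.1% were at a control S2P peak, 66.3% at a flavopiridol S2P peak and 74.6% at an auxin S2P peak. S2P peaks at a gene end rose from 39.3% to 52.5% of the list, and S5P peaks from 60.9% to 69.1%. The depth estimated from the background did not rise, being 0.857 and 0.739 of the control for S2P and S5P.

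By gene, S2P was at an end of 5855 genes in the control and 8356 in flavopiridol, and 4179 genes had it in both. In only 1159 of those 4179 did the strongest S2P peaks of both lists overlap, so most of these genes had their strongest S2P peak elsewhere. S5P went from 3525 to 5620 genes, with 3171 new and 1076 lost. New S5P peaks were strongest at Pdhb, Prkrip1, Map2k4, Uqcrc1, Trappc8, Mrpl32, Psma2, Swi5, Golga2 and Entr1, with folds from 18.2 to 16.2. Pdhb and Uqcrc1 encode mitochondrial enzymes of pyruvate oxidation and the respiratory chain, Mrpl32 a mitochondrial ribosomal protein and Psma2 a proteasome subunit. S5P was lost at Neurog1, Rad51ap2, Eid1, Bnip3, Rcn2, H2bc6, Capn7, Arid5a, Zfp959 and Pnpla8, with control folds of 11.1 to 8.10. Kept S5P peaks were led by Wls, Lars2, Cers5, Oasl1, Tmem107, Eapp, Rdm1, Zfp868, Nabp1 and Gzmk, 5 of them in regions found in all lists. New S2P peaks were at Eif3j2, Rpl37rt, Tln2, Lrrc28, Ttc23, Rps27rt, Bbs2, Poglut2, Bivm and Abhd10 (folds 15.1 to 9.78), and S2P was lost at Xkrx, Fam89b, Nsmf, Rusc1, Esx1, Naprt, Zfp61, Ppic, Cmya5 and Map4k2. Kept genes were led by Wls, Asmt, Gzmk, Oasl1, Vmn2r29, H2bc1, H2ac1, Znrd2, Cers5 and Pnpla7.

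Among the fixed lists, all 15 immediate early genes had an S2P peak at an end in flavopiridol, 11 kept and 4 gained (Egr1, Myc, Atf3 and Zfp36), at the 98.7th and 99.8th percentiles. Housekeeping genes kept S2P in 10 of 12 and gained 3 of 3 (Hspa8, Npm1 and Tbp), a gain at the 99.1th percentile, and pluripotency genes kept 11 of 14, among them Sox2, Klf4 and Tfcp2l1, and gained Pou5f1 and Klf5, at the 70.9th and 66.2th percentiles. The CTCF and cohesin list kept 6 of 7 and gained 4 of 6, at the 97.4th percentile. Lineage genes kept 1 of 3 and gained 0 of 12, at the 1.31th percentile, fibroblast genes kept 0 of 1 and gained 1 of 14, and imprinted genes kept 2 of 3 and gained 4 of 12, at the 42.0th and 71.7th percentiles. For S5P, pluripotency genes gained 6 of 13 (Sox2, Klf4, Klf5, Zfp42, Fgf4 and Tet1), at the 99.1th percentile, and kept 3 of 7, at the 8.35th, with Nanog, Klf2, Esrrb and Tdgf1 not kept. Immediate early genes gained 3 of 5 and kept 8 of 10, housekeeping genes kept 12 of 14 without Actb and Ldha, imprinted genes gained 4 of 13, lineage genes 1 of 12, fibroblast genes 0 of 12 and CTCF and cohesin genes 1 of 8.

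After auxin the S5P and S2P lists changed length in opposite ways. Each change compares 1 library with 1 library, and its cause was not tested. The S5P list shrank to 1905 peaks with 25.9% (24.8 to 27.1) of control peaks kept, at 1.201 times the control depth. The background pileup of the auxin S5P library was 0.857 of the control's, at which 81.9% would have been kept. The S2P list lengthened to 21398 peaks, with 57.2% (56.4 to 57.9) of control peaks kept and 58.3% of the list new, at 0.962 of the control depth. With lists of equal length the S5P shares kept were 56.6% in auxin and 42.7% in flavopiridol. Each pair was cut to its own shorter list, so the first covers the 1905 strongest control peaks and the second all 5449. These shares therefore give no order between the treatments. With an overlap of 50% of both peaks 36.9% of S2P peaks were kept in auxin. Both lists had S5P at 760 of 3525 genes and S2P at 4909 of 5855, with overlapping strongest peaks at 665 and 3050 of them, and S2P was gained at 3271. S2P peaks new in auxin were strongest at Fam117a, Abi1, Lrrc28, Ttc23, Spg11, Taf13, Capg, Mylip, Upf3b and Nabp1 (folds 8.29 to 6.86). Taf13 encodes a subunit of the general transcription factor TFIID and Upf3b a factor of nonsense-mediated decay. Those lost were Rapgef3, D17H6S53E, Gsdma3, AV320801, Coa3, Loxl2, R3hcc1, Mgat5b, Camk2n1 and Car15, and those kept were led by Xkrx, Wls, Asmt, Gzmk and Oasl1. S5P was lost at Bnip3, Rcn2, Capn7, Glce, Arid5a, Zfp959, Insig1, Simc1, Uchl1 and Zdhhc13 (folds 10.1 to 8.57), and new peaks were at Slc22a29 and Clcn4.

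In auxin, S5P was kept in 10 of 14 housekeeping genes, such as Gapdh, Eef1a1, Eef2 and Ncl, and in 7 of 10 immediate early genes, such as Fos, Junb, Egr1 and Ier2, at the 100th and 99.95th percentiles of random lists. Random lists were not matched for peak strength. Over all control S5P peaks the share kept ran from 13.0% in the second-lowest decile by fold to 87.1% in the top decile. S5P was kept in 0 of 7 pluripotency, 0 of 3 lineage, 0 of 2 imprinted, 1 of 3 fibroblast and 1 of 5 CTCF and cohesin genes. S2P was kept in all 14 pluripotency genes and gained in 3 of 6 (Klf5, Dppa3 and Nr0b1), kept in all 12 housekeeping and 11 immediate early genes, and kept in 7 and gained in 4 of the 13 CTCF and cohesin genes (Ctcf, Smc3, Stag1 and Pds5b, at the 98.99th percentile). Imprinted genes kept 2 of 3, fibroblast genes 1 of 1 and lineage genes 1 of 3, the last at the 3.70th percentile, and lineage genes gained 0 of 12, at the 3.43th.

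In the share of control peaks kept, the combined treatment was nearer to auxin for CTCF and RAD21 and to flavopiridol for S5P. The CTCF lists of auxin and of both drugs were nevertheless unlike. Of auxin CTCF peaks, 41.4% (39.3 to 43.5) were kept with both drugs, and 67.6% of the combined list was absent from auxin. Peaks at a gene end made up 21.2% of the combined CTCF list and 4.42% of the auxin list. CTCF was kept at 2.52% (2.41 to 2.64) of control peaks in a list of 2746, and RAD21 at 18.9% (18.5 to 19.4) in a list of 5794, below the 28.4% of auxin alone at a greater depth (1.67 times the control). Of auxin RAD21 peaks, 51.4% (50.3 to 52.5) were kept when flavopiridol was added. S5P was kept at 50.6% (49.2 to 51.9) in a list of 7496, and 64.9% (62.7 to 67.0) of the auxin S5P peaks were kept. S2P was kept at 13.8% (13.3 to 14.4) of control and 20.2% (19.7 to 20.8) of auxin peaks, in a list of 8543. With lists of equal length, 16.1% of control CTCF and 48.1% of control RAD21 peaks were kept, and 30.8% of auxin S5P and 35.9% of auxin S2P peaks. With an overlap of 50% of both peaks, the shares were 0.219% of control CTCF peaks and 8.91% of control and 11.996% of auxin S2P peaks. The median CTCF peak with both drugs was 66 bp wide, too narrow to cover 50% of the smallest control CTCF peak of 154 bp. RAD21 peaks at S5P peaks numbered 750, against 751 in the control. In the shorter RAD21 list they made up 12.9% (12.1 to 13.8), or 8.36% without the regions found in all lists.

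CTCF peaks were at an end in both lists at 491 genes, with overlapping strongest peaks at 360, led by Map3k15, Lsm11, Thg1l, Rbm17 and Rapgef1, and were lost at Ddx47, Rab2b, Tox4 and Erc2. RAD21 was lost at Abca14, Ebf1, a B-cell transcription factor gene, and Slc4a3, kept at Wls, Oasl1 and Arhgap22, and new at Fgf1 and Snx19. New S5P peaks were strongest at Msmo1, Ireb2, Fasn, Susd6, Gucd1, Snrpd3, Siah1b, Tomm40, Sptlc1 and Tspyl1 (folds 18.7 to 16.8), Msmo1 and Fasn being enzymes of sterol and fatty acid synthesis. Relative to auxin alone, S5P was new at 4637 genes, led by Rbm8a, Tjap1, Clpb and Msmo1. S2P was lost from 4013 of 5855 control genes, among them Xkrx, Pnpla7, Nsmf and Bex1, and new at Slc16a10, Rad51ap2 and Mylip. In only 613 of the 1842 genes with S2P in both lists did the strongest peaks overlap. Housekeeping genes kept S2P in 10 of 12, at the 99.99th percentile, and immediate early genes in 7 of 11, at the 98.3th, while pluripotency genes kept 3 of 14 (Klf2, Klf4 and Tfcp2l1), at the 22.8th. The other lists kept S2P in 3 of 7 CTCF and cohesin, 1 of 3 imprinted, 0 of 3 lineage and 0 of 1 fibroblast genes. S5P was kept in 12 of 14 housekeeping, 9 of 10 immediate early, 3 of 7 pluripotency, 4 of 5 CTCF and cohesin, 2 of 3 lineage, 2 of 3 fibroblast and 1 of 2 imprinted genes. CTCF was kept in 3 housekeeping genes (Eef1a1, Eef2 and Ncl) and in 1 imprinted gene (Meg3), and in 0 genes of the other lists. RAD21 was kept in 4 of 8 imprinted, 2 of 6 CTCF and cohesin, and 1 gene each of the pluripotency, lineage, fibroblast and housekeeping lists, and 0 of 3 immediate early genes.

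TOP2B, which relieves torsional stress in DNA, was placed against the other lists to see which chromatin features it shared. Of 7380 TOP2B peaks, 76.0% (75.0 to 77.0) were at the end of a protein-coding gene. They overlapped CTCF peaks in 39.4% (38.3 to 40.5), S5P peaks in 24.5% (23.5 to 25.5), S2P peaks in 12.7% (11.9 to 13.5) and RAD21 peaks in 6.64% (6.08 to 7.23). The highest values in shifted lists were 3.27%, 0.407%, 0.921% and 1.33%. TOP2B overlapped S2P peaks of the auxin list in 44.3%, of the flavopiridol list in 55.5% and of the list with both drugs in 23.5%, and S5P peaks in 6.94%, 39.1% and 36.9%. A TOP2B peak was found in or at 12 of 15 lineage genes, such as Gata6, Foxa2, Sox17 and Pax6, 11 of 13 CTCF and cohesin genes, 10 of 15 housekeeping genes and 9 of 15 immediate early genes, at the 99.99th, 99.99th, 99.6th and 98.4th percentiles of lists drawn from all genes. Imprinted genes (6 of 15), pluripotency genes (6 of 20) and fibroblast genes (2 of 15) were at the 73.0th, 42.1th and 5.81th. With lists of equal length the shares were 23.9% for S5P, 8.52% for CTCF and 1.36% for RAD21. For S5P this covered the 5449 strongest TOP2B peaks, and for the others all 7380. With an overlap of 50% of both peaks the shares were 9.44% for S5P, 8.58% for CTCF and 1.19% for RAD21.

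Genes with TOP2B at a single end gave a way to tell their ends apart. Among 4710 genes of at least 10 kb with a TOP2B peak at exactly 1 end, S2P in the control was found at the TOP2B end in 14.7% (13.7 to 15.7) and at the other end in 27.1% (25.8 to 28.4). In flavopiridol the shares were 63.9% and 3.91%, in auxin 51.6% and 26.1%, and in both drugs 28.2% and 1.55%. S5P was at the TOP2B end in 26.5% of these genes in the control, 5.14% in auxin, 43.5% in flavopiridol and 41.4% in both, and at the other end the highest value was 3.67%, in the control. CTCF was at the TOP2B end in 48.7% and at the other end in 12.7% in the control, and in 23.8% and 9.13% in flavopiridol. RAD21 went from 9.07% to 10.3% at the TOP2B end and from 5.01% to 5.50% at the other.

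**Figure D3:**
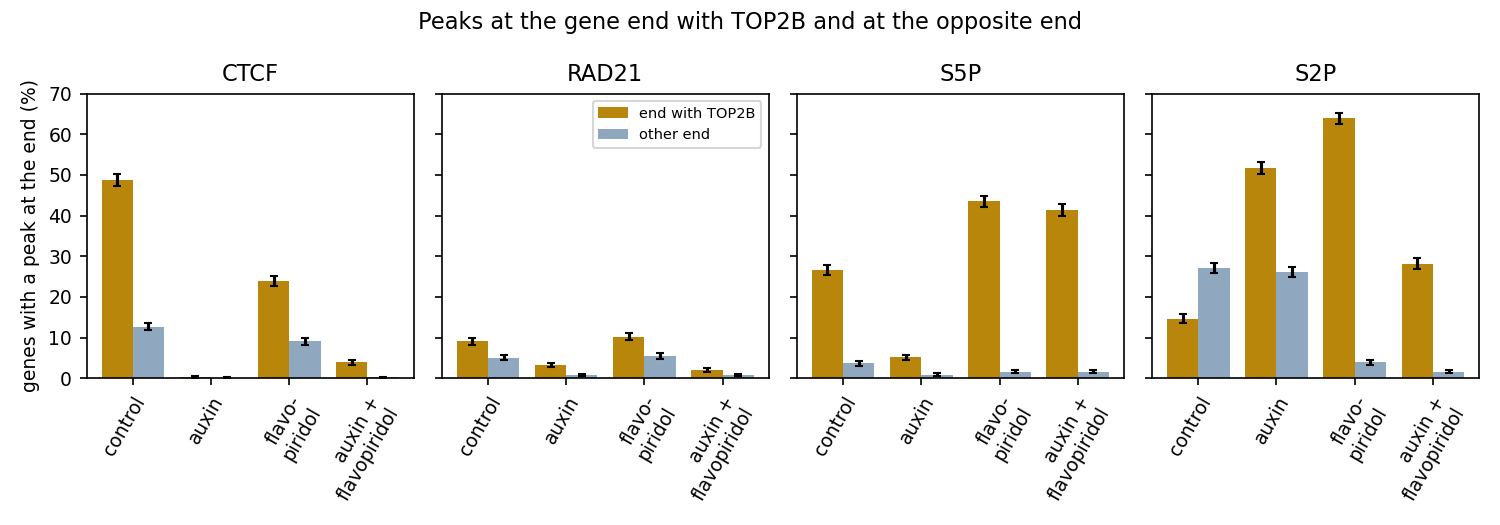
Percent of 4710 genes with a TOP2B peak at exactly 1 end that had a peak at that end or at the other end (vertical axis), for 4 antibodies and 4 conditions, 1 library each, with exact binomial 95% intervals. S2P at the TOP2B end goes from 14.7% in the control to 63.9% in flavopiridol while the other end goes from 27.1% to 3.91%.

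In HCT116 cells, decitabine removes DNA methylation, which can block CTCF from its motif, and the comparison asked where CTCF, cohesin and polymerase peaks differed after it. CTCF and SMC3 were largely retained. Of 56091 control CTCF peaks, 90.9% (90.7 to 91.1) were kept, and of 45704 SMC3 peaks 84.9% (84.5 to 85.2). H3K4me3, a mark of active promoters, was kept at 77.4% (76.9 to 77.8) of 29303 peaks, and S5P at 50.9% (50.1 to 51.7) of 14535. Peaks absent from the control made up 11.1% of the DAC CTCF list, 16.3% of SMC3, 22.8% of H3K4me3 and 45.4% of S5P. The DAC S5P library had 0.506 of its control's depth and 0.645 of its background pileup. At that background pileup 82.0% would have been kept. In the top 6 deciles by fold, at least 99.57% of CTCF peaks were kept.

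**Figure D4:**
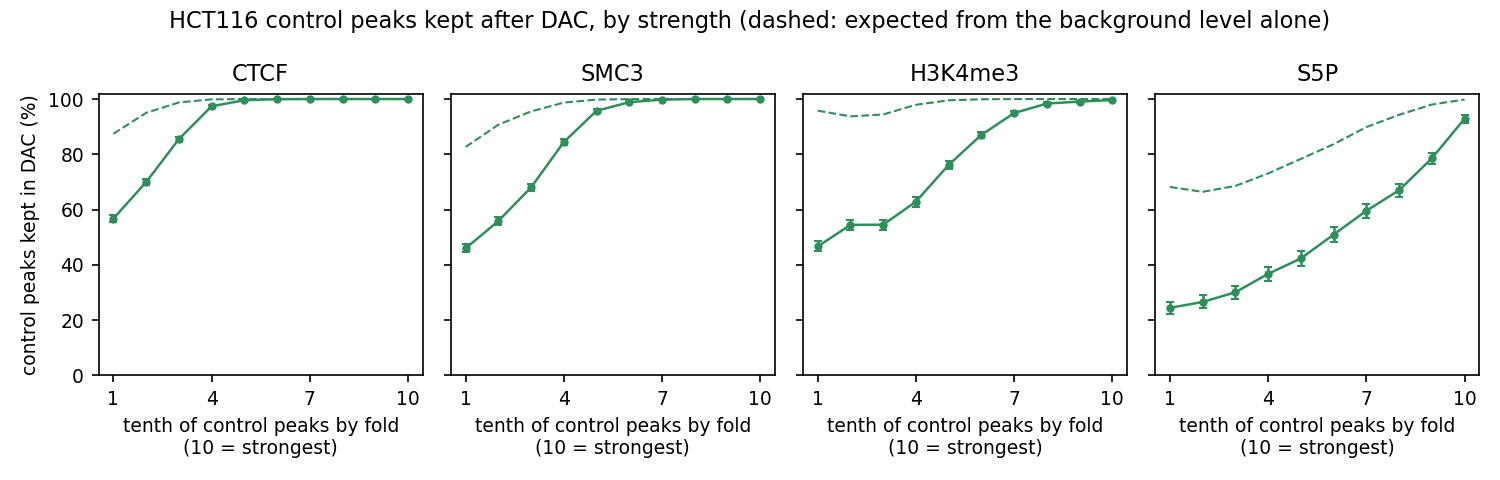
Percent of HCT116 control peaks kept after DAC (vertical axis) by decile of the control list ranked by fold (horizontal axis, 10 being the strongest), for 4 antibodies, 1 library per condition. Points carry exact binomial 95% intervals and dashed lines give the share expected if only the background level differed; CTCF runs from 56.7% in the lowest decile to 100% in the top decile, and S5P from 24.4% to 92.8%.

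Differences were confined mostly to weak sites for CTCF and SMC3. Of 44153 control CTCF peaks with an expected probability over 99%, 523 were absent from DAC, 1.18%, and of 44245 such DAC peaks 681 were absent from the control, 1.54%. The matching shares of control peaks absent from DAC were 1.85% for SMC3, 10.8% for H3K4me3 and 11.0% for S5P, and of DAC peaks absent from the control 2.72%, 7.19% and 37.0%. The strongest DAC-only CTCF peaks (hg19) were on chromosome X at 18917993 to 18918248, chromosome 16 at 6066563 to 6066801, chromosome 12 at 112699426 to 112699690, chromosome 15 at 65197754 to 65198022 and chromosome 11 at 78549528 to 78549761, with folds of 13.6 to 11.0. The strongest control-only CTCF peak, on chromosome 7 at 82254777 to 82255018, had a fold of 12.1, and the strongest kept, on chromosome 9 at 100173850 to 100174312, a fold of 35.0. DAC-only H3K4me3 peaks were led by chromosome 2 at 16846151 to 16846947 and at 905001 to 906119, with folds of 12.7 and 12.2. The strongest DAC-only S5P peaks were on chromosome 20 at 60551958 to 60552431 (fold 21.1) and at 8137223 to 8137664 (fold 18.1). For SMC3 the strongest DAC-only peak was on chromosome 19 at 3700519 to 3700769 (fold 9.97) and the strongest control-only peak on chromosome 3 at 178749636 to 178749807 (fold 10.3).

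Few CTCF peaks gained with DAC were at gained H3K4me3. Of 6396 DAC-only CTCF peaks, 62 were at a DAC-only H3K4me3 peak, 0.969%, against 1.15% of 51038 kept peaks, a difference of −0.185 points (−0.418 to 0.101). Its interval lay below 0 at a −log10 q of at least 5 (−0.314, −0.513 to −0.0492), with an overlap of 50% of both peaks (−0.235, −0.340 to −0.0930) and with lists of equal length (−0.885, −1.15 to −0.459). DAC-only CTCF peaks were at an SMC3 peak in 16.7% (15.8 to 17.6), or 28.8% with lists of equal length, against 74.2% of kept peaks, and 17.0% of the 5101 CTCF peaks seen only in the control were at a control SMC3 peak. S5P peaks seen only in DAC were at a DAC-only H3K4me3 peak in 10.6% (9.84 to 11.4) of 6054 cases, against 2.55% of kept S5P peaks. In the opposite direction, control-only S5P peaks were at a control-only H3K4me3 peak in 5.71% of 7140 cases, against 3.96% of kept peaks.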

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

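The tests of regions found in all lists for CTCF, of exchanged libraries and of S2P depth were chosen only after the results they address had been seen. The bounds for the other tests were written before their values were computed.

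The length of a list after flavopiridol, relative to the list without it, moved in opposite ways in cells without and with auxin. For CTCF the ratio was 0.702 without auxin and 1.24 with it, for RAD21 1.12 and 0.688, and for S2P 1.10 and 0.399. For S5P both ratios were above 1, at 1.45 and 3.93. What drew attention was the opposite direction between the groups. Each ratio compares 1 library with another, and the difference was not tested. For CTCF the auxin library had 0.602 of the control depth and the library with both drugs 1.09, which favours a longer list with both: at the auxin background level, 70.9% of its peaks would have been called.

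Fewer CTCF peaks were listed in auxin, and the auxin library was shallower with a shorter fragment length. If that were the whole cause, the top decile of control peaks would have been kept at 80% or more of the expected share, and it was kept at 3.79% of it, which rules out the background level as the whole cause. Regions listed for every antibody held 30.6% of the kept CTCF peaks, between the bounds of 10% and 50% set for the test, so part of what remained may be such regions and their weight is undecided. Degradation of CTCF is the biological explanation the design gives, and protein levels were not analysed here.

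Fewer RAD21 peaks were listed in auxin. For depth as the cause, the bound set beforehand was that the top decile be kept at 80% or more of the expected share, and the value was 80%, which met that bound. Depth was nevertheless judged unlikely as the whole cause on other values, a rule set after this one was seen. The auxin library had an estimated 1.13 times the control depth, and 8 of 10 deciles were kept at under 50% of the expected share. That estimate assumes like background reads in both libraries, which was not checked. Sites with CTCF were kept more often by 4.15 points on average within deciles, but this does not decide whether loss of CTCF acted site by site: the same difference was 5.98 points in flavopiridol, without auxin, and 79.5% of the sites without control CTCF had a CTCF peak in flavopiridol. The bound of 0 set beforehand for that test was therefore wrong, and loss of CTCF at the site stays open.

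S2P peaks lay at S5P peaks more often in flavopiridol, at 38.1% against 14.4%. Flavopiridol S2P peaks were at the control S5P list in 21.03%, and control S2P peaks at the flavopiridol S5P list in 8.74%. The rise can therefore not be assigned to either list alone. If the S2P and S5P libraries had been exchanged, the list labelled S5P would hold more of the control S2P peaks. It held 8.74% against 19.5% for the list labelled S2P. Of control S5P peaks, 66.3% were in the S2P list and 51.8% in the S5P list, which met the other part of that prediction. The flavopiridol S2P list was larger, at 16773 peaks over 12.3 Mb against 7896 over 2.68 Mb for S5P, and held more of both control lists. The test therefore cannot decide on an exchange. The estimated depth was 0.857 of the control's, which gave no sign of more reads. That estimate is taken from the background and is not a read count, so more reads are not excluded. Outside the regions found in all lists the rise was still 24.2 points. The auxin S2P list, without flavopiridol, held 74.6% of control S5P peaks, so S2P at S5P sites is not particular to flavopiridol. Inhibited elongation is the biological explanation the design gives, and it stays open, as does antibody cross-reaction, which was not tested.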

How the results depend on the processing

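No paired analysis was possible because each ChIP-seq group holds 1 library per antibody; the replicate numbers shared in the labels belong to libraries not analysed here. For the same reason no replicate could be left out. Of 28 results, 6 stayed within their interval at a −log10 q of at least 5, 4 with 50% overlap, 3 at equal length and 10 without the regions found in all lists. At the stricter q, 14 rose and 8 fell beyond it, with 50% overlap 1 and 23, at equal length 12 and 13, and without the regions 0 and 18. The gene windows of 500 and 2000 bp each left 8 of 8 counts of listed genes within 1.5 times. No difference whose interval excluded 0 changed sign. A share has no sign, and the order of some shares turned with 50% overlap. TOP2B was at CTCF in 39.4% and S5P in 24.5%, but in 8.58% and 9.44% with 50% overlap. S2P was kept at 19.5% in flavopiridol and 13.8% with both drugs, but at 8.61% and 8.91% with 50% overlap. The share of RAD21 peaks at S5P peaks in flavopiridol minus control, whose interval included 0, changed from −0.140 to 0.0156 without the regions; the rule that such a change is not a reversal was set after it was seen. The DAC-only H3K4me3 difference, whose interval included 0, lay below 0 with its whole interval at a −log10 q of at least 5 (−0.314), with 50% overlap (−0.235) and at equal length.

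With a −log10 q of at least 5, the share kept was 62.3% (flavopiridol) and 2.08% (both drugs) for CTCF, 23.7% (auxin) and 90.6% (flavopiridol) for RAD21, 30.8%, 58.3% and 58.3% (auxin, flavopiridol, both) for S5P, and 59.5% (auxin) and 22.2% (flavopiridol) for S2P. In DAC it was 92.5% for CTCF, 88.7% for SMC3, 78.0% for H3K4me3 and 52.2% for S5P. Of auxin peaks, 58.8% of RAD21 and 70.8% of S5P were kept with both drugs. RAD21 sites with CTCF exceeded those without by 8.86 points in auxin and 6.28 in flavopiridol, and RAD21 at S5P in auxin exceeded the control by 7.11. TOP2B was at CTCF in 29.999%, RAD21 in 5.12% and S5P in 17.8%, and DAC-only CTCF at SMC3 in 14.5%. The cause was not tested.

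With an overlap of at least 50% of both peaks, the shares kept in auxin, flavopiridol and both were 0.106%, 50.4% and 0.219% for CTCF, 21.01%, 85.5% and 13.4% for RAD21, 17.9%, 38.0% and 38.1% for S5P, and 36.9%, 8.61% and 8.91% for S2P. In DAC they were 87.8% for CTCF, 79.96% for SMC3, 68.1% for H3K4me3 and 37.7% for S5P. Of auxin peaks, 47.4% of RAD21, 50.2% of S5P and 11.996% of S2P were kept with both drugs. The CTCF difference for RAD21 in flavopiridol was 17.0 points, TOP2B was at CTCF in 8.58%, RAD21 in 1.19% and S5P in 9.44%, and DAC-only CTCF at SMC3 in 14.3%. A kept share can only fall under this rule, by its construction. For CTCF the median widths of 53 bp in auxin and 66 bp with both drugs, against a smallest control peak of 154 bp, kept most peaks from meeting it.

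With lists of equal length, the shares kept in auxin, flavopiridol and both were 7.40%, 70.9% and 16.1% for CTCF, 60.9%, 84.8% and 48.1% for RAD21, and 56.6%, 42.7% and 43.0% for S5P, and for S2P 48.4% in auxin and 17.9% in both. Each comparison was cut to its own shortest list, so these shares cover different numbers of control peaks and give no order between conditions. In DAC they were 90.2% for CTCF, 84.4% for SMC3, 76.8% for H3K4me3 and 53.8% for S5P. Of auxin peaks, 64.2% of RAD21, 30.8% of S5P and 35.9% of S2P were kept with both drugs. The CTCF difference for RAD21 in flavopiridol was 8.85 points, and RAD21 at S5P differed from the control by 10.8 points in auxin and −0.716 in flavopiridol. TOP2B was at CTCF in 8.52% and RAD21 in 1.36%, DAC-only CTCF at SMC3 in 28.8%, and the DAC-only H3K4me3 difference was −0.885 points. The cause was not tested.

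Without the regions found in all lists, chosen after seeing the data, the share kept was 0.919% (auxin) and 2.13% (both) for CTCF, 27.6% and 18.0% for RAD21, 21.8%, 49.1% and 47.9% (auxin, flavopiridol, both) for S5P, and 56.4%, 17.99% and 12.2% for S2P. In DAC it was 90.5% for CTCF, 84.2% for SMC3, 75.5% for H3K4me3 and 44.8% for S5P. Of auxin peaks, 49.6% of RAD21, 58.5% of S5P and 19.1% of S2P were kept with both drugs, and RAD21 at S5P in auxin exceeded the control by 2.59 points. CTCF sites with S5P minus those without gave 6.95 points in auxin, 20.05 in both and −10.6 in flavopiridol, against 21.3, 32.2 and −2.30 with the regions, and sites with RAD21 exceeded others by 0.937 in auxin and 3.04 in both, against 2.17 and 4.24. For S5P and RAD21 the fall of these differences follows from construction, since such regions hold a peak in every list. Otherwise the cause was not tested.

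Depth limits the weak sites most. At the background level of the auxin CTCF library 40.9% of control peaks would have been kept without any loss, and for S5P 82.0% in DAC and 73.5% in flavopiridol.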

Other observations

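The test below was written after the overlap of S2P with TOP2B had been seen, but before the values at each gene end were computed.

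The hypothesis was that in flavopiridol S2P peaks leave the gene end away from TOP2B and appear at the end with TOP2B. The share of genes with an S2P peak at the TOP2B end rose by 49.3 points from control to flavopiridol, and the share at the other end fell by 23.2 points. The rise restates the overlap seen before, since the share of TOP2B peaks at S2P peaks had risen by 42.9 points, and it is no independent test. The hypothesis stays open. In auxin without flavopiridol the TOP2B end also rose, by 36.9 points, while the other end changed by −0.998, so the rise is not particular to flavopiridol. With both drugs the changes from control were 13.5 and −25.6 points. Which end is the transcription start was not determined here, and 1 library per condition was compared.

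Regions holding a peak in all 16 mouse lists made up between 280 and 341 peaks per list, which was 15.4% of the auxin CTCF list and 0.404% of the control CTCF list. Of TOP2B peaks, 21 lay in such regions.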
